A study of Homo sapiens with 13 samples.

How the data were processed

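RNA from MCF10A cells, deprived of serum for 24 h and then left unstimulated or stimulated with EGF or with the serum mixture, was measured by the authors on 13 Affymetrix arrays of 22277 probe sets, 1 array per stimulus and time. The deposited table holds 1 intensity per probe set and array, the MAS5 signal on a linear scale, which per the labels came from MAS5; the version was not given in the sources used here. The authors had scaled each array to the same mean: after trimming 2% at each end, the mean signal was 150.04 to 150.05 on the 13 arrays. Detection calls were not used here. The share of probe sets with a signal under 20 was 33.3% on the serum array of 20 min and 36.7% to 40.0% on the others, and the 3' to 5' signal ratio of the actin control was 1.31 to 1.79. The EGF array of 20 min was described as 20 min in its title and as 40 min in its description; the title was used.

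Values were transformed as log2 of signal plus 6, the offset being the 20th percentile of the deposited values rounded to a whole number. The offset rule, the filter, the models, the gene lists and the naming of genes were set before the data were examined. The medians of the 13 arrays as deposited ran from 5.4 to 5.7, a spread of 0.3 above the preset limit of 0.2, so the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Of 22215 probe sets other than 62 controls, 19064 carried 1 gene symbol, 1043 several and 2108 none here; symbols came from the platform annotation, and 19058 were matched to the reference table by Entrez number, with 0 given a newer symbol. Each of 11963 genes was represented by its probe set with the highest mean, whose choice did not use the groups. Genes were kept when that mean reached the 40th percentile of probe set means (4.68), which left 7731.

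Linear models were fitted with limma (lmFit and eBayes), and p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Each time's mean of EGF and serum was compared with the unstimulated array in a model with time and stimulus as additive terms (5 residual degrees of freedom). Late arrays (120, 240 and 480 min) were compared with early ones (20, 40 and 60 min) over both stimuli and in each (8 residual degrees of freedom), and the stimulus by phase interaction was fitted with time as a block (4). EGF was compared with serum with time as a block over all 6 times (5) and in its early and late parts (4). The genes named were, among those past the threshold, the 5 largest rises and 3 largest falls at each response time, the 10 largest each way for late minus early, the 12 largest each way for EGF minus serum and the 5 largest each way for the interaction. Up to 4 members of each list past the threshold, otherwise the 2 with the largest difference, were added as values, and FOS, EGR1, MYC, DUSP6 and HBEGF in every comparison. As exceptions chosen later, the EGF-minus-serum rule was used also for its early and late parts, 10 each way for late minus early within each stimulus, and some near-threshold genes were named as values.

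Gene lists, 27 in all and 26 with at least 5 tested genes, were tested with camera at an inter-gene correlation of 0.01 and with the correlation estimated. The rotation test fry and exact sign flips of the 6 time pairs were added later. Similarity of the EGF and serum time courses was tested by permuting the 6 time points exactly. The procedure was tested on simulated data with 200 changed genes of 7731: at a 2-fold change 42.2% were recovered in the 60 min response, 88.4% in late minus early, 83.4% in EGF minus serum, 64.8% in its late part and 34.2% in the interaction, with 4% to 7.4% false calls; at 4-fold 78.4% to 98.6% were recovered. The simulated spread was that left after fitting every time level. It holds no differences between times within a phase, so the late-minus-early recovery may be too high for the real arrays. Of 20 lists of 20 genes shifted by log2 1 in EGF minus serum, 20 were found by camera at an unadjusted p under 0.05. Of 20 unshifted lists 1 was called. The genes were simulated independently, so these figures do not cover lists of correlated genes or smaller shifts.

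Alternatives were no offset, 4 times the offset, no quantile normalization, no filter or a stricter filter on dim genes, the mean of a gene's probe sets, a variance trend with robust variances, a minimum of 1.5-fold, other codings of time, each array left out in turn, and, added later, both arrays of 20 min left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probe sets without 1 symbol were left out of the gene tests and examined separately.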

Results

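Serum-deprived MCF10A cells, a human mammary epithelial cell line, were measured on 13 arrays. There was 1 unstimulated array, and 1 array each at 20, 40, 60, 120, 240 and 480 min after EGF or after the serum mixture. That mixture of horse serum, insulin, hydrocortisone and cholera toxin is called serum below. No array had a replicate, so the EGF and serum arrays of the same time were treated as 2 samples of that time. The p-values therefore measure only the spread between these arrays. The lone unstimulated array was assumed to vary like the others, and its error was shared by the 6 comparisons against it. The number of arrays limits the precision of every estimate below. Differences are on the log2 scale and SE is the standard error. The p-values are two-sided and adjusted over the 7731 genes tested with limma unless stated otherwise.

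Within 60 min of stimulation 6 genes rose past the threshold. The means of the EGF and serum arrays (n = 2) were set against the unstimulated array (n = 1). At 40 min EGR3 (3.62, SE 0.30, 12.3-fold, adjusted p = 0.00873) and EGR1 (2.41, SE 0.21, 5.32-fold, adjusted p = 0.00873), which encode zinc-finger transcription factors, had risen. So had CCN2 (3.24, SE 0.18, 9.47-fold, adjusted p = 0.000909) and CCN1 (2.02, SE 0.23, 4.06-fold, adjusted p = 0.0381), which encode secreted matrix-associated proteins. The other rises were of PTGS2, whose product makes prostaglandins (3.10, SE 0.32, 8.59-fold, adjusted p = 0.0237), and of the ERK phosphatase DUSP5 (1.92, SE 0.23, 3.79-fold, adjusted p = 0.039). The same 6 genes were past the threshold at 60 min, where the fit with a variance trend and robust variances called 28. This contrast recovered 42.2% of simulated 2-fold changes. There EGR3 was at 3.68 (SE 0.30, 12.8-fold, adjusted p = 0.00826) and CCN2 at 3.42 (SE 0.18, 10.7-fold, adjusted p = 0.000607). EGR3 (2.99, SE 0.30, adjusted p = 0.0399) and CCN2 (2.25, SE 0.18, adjusted p = 0.0151) had already risen at 20 min. Both stayed high at 120 min, EGR3 at 2.93 (SE 0.30, adjusted p = 0.0459) and CCN2 at 2.82 (SE 0.18, adjusted p = 0.0027). The size of the EGR3 rise depended on the processing. Over the alternatives it ran from 2.698 to 4.198 at 40 min and from 2.761 to 4.267 at 60 min. For CCN2 at 40 min the range was 3.173 to 3.267.

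**Figure D1:**
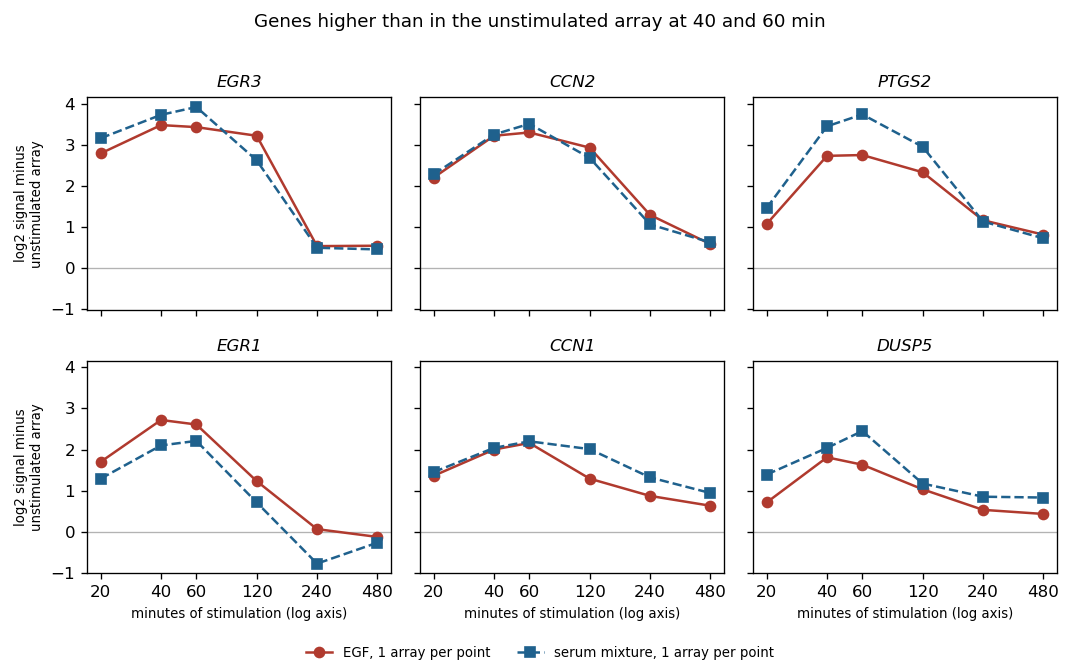
Signal of EGR3, CCN2, PTGS2, EGR1, CCN1 and DUSP5 minus that of the unstimulated array (log2) against minutes after stimulation on a log axis. Each point is 1 array, with circles for EGF and squares for serum, and at 60 min CCN2 was at 3.31 in EGF and 3.52 in serum.

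Other fast transcripts had large values with larger errors. FOS stood at 3.66 at 20 min (SE 1.13, adjusted p = 0.754) and at 4.27 at 40 min (SE 1.13, adjusted p = 0.436). FOSB was at 3.57 at 40 min (SE 0.98, adjusted p = 0.494). The cytokines IL6 and LIF were at 2.97 at 60 min (SE 0.38, adjusted p = 0.0562) and at 3.17 at 120 min (SE 0.39, adjusted p = 0.0669). MYC, a growth regulator often listed with these genes, was at 0.20 at 40 min (SE 0.33, adjusted p = 0.957).

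Of the 16 tested immediate early transcription factors, 16 were above the unstimulated array at 40 min, with a median of 1.52. Past the threshold 2 were higher (EGR1 and EGR3) and 0 lower, and 11 were higher when adjusted over the list alone. Growth-factor studies of this kind are known for these genes. The same holds for the lists of AP-1 factors, MAP kinase phosphatases, signalling attenuators, mRNA decay factors and other fast transcripts, so counts in them are not independent evidence. Of 15 cytokines and NF-kB targets, 0 were past the threshold at 60 min. With a median of 1.16, 8 of them were higher when adjusted over the list alone.

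By 240 and 480 min the immediate early list was back near its starting level. Its median against the unstimulated array was 0.04 in EGF and 0.30 in serum at 240 min, and -0.05 and -0.08 at 480 min. Against the unstimulated array limma called 0 genes at 240 min (752 at an unadjusted p under 0.05) and 0 at 480 min (910). With a variance trend and robust variances the counts were 35 and 46. On single arrays at 480 min, 117 genes were at least 2-fold higher and 173 lower after EGF, and 151 higher and 239 lower after serum. CEBPD was at -1.16 (SE 0.20, adjusted p = 0.182), TXNIP at -1.40 (SE 0.31, adjusted p = 0.22) and ODC1 at 0.88 (SE 0.16, adjusted p = 0.183) at that time.

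Counts of these comparisons rested on single arrays. The 2 calls at 20 min became 0 without either array of 20, 40 or 480 min. They became 1 without either of 60 or 240 min. The 6 at 40 min became 1 without either array of 40 min and 3 without either of 20 min. The 6 at 60 min became 1 without serum at 60 min, and 3 without EGF at 60 min or either array of 20 min. The 2 at 120 min became 1 without any stimulated array other than serum at 120 min. CCN2 was past the threshold at 40, 60 and 120 min under each omission and each processing alternative tried.

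The EGF and serum series had partly shared time courses, with no unstimulated array at a later time to set them against. Across the 6 time points alone, EGR3, CCN2 and EGR1 changed (limma, 3 genes past the threshold, 958 at an unadjusted p under 0.05). Across genes and times, the EGF and serum profiles correlated at r = 0.164, the highest of the 720 orders of the time points. The exact permutation p = 0.00139 (one-sided) is the smallest these orders can give, and the next highest r was 0.158. Without the filter on dim genes r fell to 0.063. The count of 3 became 2 without EGF at 240 min, serum at 240 min or serum at 480 min.

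Early transcription factors were lower in the late arrays than in the early ones. The late arrays (120, 240 and 480 min, n = 6) differed from the early ones (20, 40 and 60 min, n = 6) in 268 genes, 130 higher and 138 lower. This fit took the 6 arrays of a phase as separate samples, though they came from 3 times shared by EGF and serum. The EGF-receptor ligand TGFA rose (0.99, SE 0.12, 1.99-fold, adjusted p = 0.00446), while the receptor ERBB3 fell (-0.58, SE 0.12, adjusted p = 0.0337). Over the alternatives ERBB3 ran from -0.66 to -0.232, and its call was lost in 10 single-array omissions and with the mean of its probe sets. Cyclin D1, which drives entry into the cell cycle, was higher late than early as well (CCND1, 0.67, SE 0.15, adjusted p = 0.036). Against the unstimulated array CCND1 was at -0.18, -0.44 and -0.48 early and at -0.08, 0.45 and 0.55 late, so part of the difference was an early dip. Another bright probe set of CCND1 was at 0.38 late minus early and below the unstimulated array at every time. The CCND1 call was lost in 9 single-array omissions and with the mean of its probe sets. The glucose transporter SLC2A3 (2.01-fold, log2 SE 0.19, adjusted p = 0.0237) and the collagen receptor subunit ITGA2 (0.92, SE 0.17, adjusted p = 0.0212) rose too. The retinoid-producing enzyme ALDH1A3 (1.30, SE 0.25, 2.46-fold, adjusted p = 0.0239) and the activin antagonist FST (1.02, SE 0.19, adjusted p = 0.0234) were also higher late.

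Transcription factors of the first wave fell. FOS (-2.58, SE 0.58, adjusted p = 0.0389), FOSB (-2.58, SE 0.51, adjusted p = 0.0254) and EGR3 (-2.11, SE 0.51, adjusted p = 0.0485) were lower late. So were EGR1 (-1.97, SE 0.32, adjusted p = 0.0165), ATF3 (-1.88, SE 0.39, adjusted p = 0.0292) and the neutrophil chemokine CXCL2 (-2.00, SE 0.19, adjusted p = 0.0029). Transcripts linked to growth arrest and to p53 fell too. They were the repressor BCL6 (-1.37, SE 0.22, adjusted p = 0.0164), the inhibitor of glucose uptake TXNIP (-0.93, SE 0.22, adjusted p = 0.048) and MDM2 (-0.89, SE 0.12, adjusted p = 0.00927).

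Fixed gene lists turned the same way. Some of them hold genes named above, such as FOS, FOSB, EGR1, EGR3 and ATF3 in the immediate early list, so those lists are not separate support. Among 16 immediate early factors (median -0.85), 0 were higher and 6 lower past the threshold, and 9 were lower when adjusted over the list alone. By camera the list had an adjusted p = 5.13e-06, and adjusted p = 0.412 with an estimated correlation. All 19 ribosome biogenesis and MYC targets had positive values (median 0.17), with 2 higher past the threshold and 7 when adjusted over the list alone. Camera gave an adjusted p = 1.43e-05 for them, and adjusted p = 0.204 with an estimated correlation. The 2 were NIP7 (0.54, SE 0.11, adjusted p = 0.0291) and PUS7 (0.50, SE 0.09, adjusted p = 0.0219). The 14 glycolysis and glucose uptake genes had a median of 0.09 and 1 gene past the threshold. Their camera test gave an adjusted p = 0.0458, and adjusted p = 0.412 with an estimated correlation.

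Lists that were lower late included the 14 glucocorticoid targets (1 higher, 7 lower, median -0.49). For this list camera gave an adjusted p = 0.000267, and adjusted p = 0.204 with an estimated correlation. In this list ZBTB16 (-1.25, SE 0.18, adjusted p = 0.0106), DUSP1 (-1.20, SE 0.12, adjusted p = 0.00393) and SGK1 (-1.14, SE 0.15, adjusted p = 0.00927) fell. ANGPTL4 rose (0.96, SE 0.16, adjusted p = 0.0165). These values pool both stimuli, which differed for some members. ZBTB16 was at -2.65 in EGF and 0.14 in serum, and ANGPTL4 at -0.15 and 2.08. DUSP1 (-1.55 and -0.85) and SGK1 (-1.02 and -1.27) were lower late in both. Against the unstimulated array the list's mean was -0.03 early and -0.84 late in EGF, and 0.38 and 0.29 in serum. Of 17 FOXO and growth arrest genes, 0 were higher and 3 lower (median -0.26), and of 11 p53 targets 0 and 2 (median -0.27). Camera gave an adjusted p = 0.00277 for the former and 0.021 for the latter, and adjusted p = 0.204 with an estimated correlation for both. Of 15 cytokines and NF-kB targets, 0 were higher and 2 lower (median -0.33, camera adjusted p = 0.0107, and adjusted p = 0.493 with an estimated correlation). So 7 of 26 lists passed at the preset correlation and 0 of 26 with an estimated one.

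The remaining lists were not past the threshold by camera in the late-minus-early comparison. Counts past the gene threshold (higher and lower) were 0 and 1 for AP-1 and delayed early factors. They were 1 and 1 each for MAP kinase phosphatases, other attenuators, and EGF family ligands and receptors. They were 0 and 0 each for mRNA decay factors, other fast transcripts, and SRF, MRTF and YAP targets. Camera adjusted p for these 7 ran from 0.0761 to 0.996. Counts were 0 and 1 for cAMP and CREB targets (adjusted p = 0.0527), 1 and 0 for G1 and S phase genes (0.0614) and 0 and 0 for G2 and M phase genes (0.109). Proteolysis, matrix and migration genes had 2 and 0 (0.0567) and stress response genes 1 and 0 (0.0674). TGF-beta targets and cholesterol synthesis genes each had 0 and 0 (0.408), as did interferon response genes (0.996). Basal markers had 1 and 0 (0.553), luminal markers 0 and 1 (0.996) and keratinocyte differentiation markers 1 and 0 (0.561). Housekeeping genes had 0 and 0 (median 0.05, adjusted p = 0.497). Of 4 tested markers of other cell types 1, CD14, fell (-0.79, SE 0.15, adjusted p = 0.0219).

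The 6 arrays of each phase came from 3 times, and with time as a factor the count was 147. Among the genes named above, the calls of FOS (adjusted p = 0.0549), ATF3 (adjusted p = 0.0642), MDM2 (adjusted p = 0.0684), ERBB3 (adjusted p = 0.0697), ZBTB16 (adjusted p = 0.196) and ANGPTL4 (adjusted p = 0.238) ended there. The count of 268 genes was also sensitive to single arrays. It was 108, 79, 93 and 75 without EGF at 20, 40, 240 and 480 min. It was 154, 56, 157, 437 and 100 without serum at 20, 40, 60, 120 and 240 min.

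Within each stimulus the same contrast (n = 3 late against 3 early arrays) was past the threshold for 20 genes after EGF (6 higher, 14 lower) and 103 after serum (54 higher, 49 lower). After EGF, the EGF-receptor ligands EREG (1.31, SE 0.22, adjusted p = 0.0492) and TGFA (1.24, SE 0.16, adjusted p = 0.0153) rose. The EREG call was lost in 11 single-array omissions and without the filter on dim genes, and the TGFA call in 3 omissions. The stress pseudokinase TRIB3 (1.41, SE 0.20, adjusted p = 0.0202) and the ERK-pathway inhibitor SPRED2 (0.85, SE 0.12, adjusted p = 0.0177) rose too. Over the alternatives SPRED2 ran from 0.153 to 0.909, and its call was lost in 4 single-array omissions and with the mean of its probe sets. ZBTB16 (-2.65, SE 0.25, 6.26-fold, adjusted p = 0.00312), SOCS1 (-1.63, SE 0.20, adjusted p = 0.0132) and the PI3K subunit PIK3R1 (-1.07, SE 0.16, adjusted p = 0.0306) fell. After serum, ANGPTL4 (2.08, SE 0.22, 4.22-fold, adjusted p = 0.00612) and the tight-junction protein OCLN (1.58, SE 0.26, adjusted p = 0.0251) rose. FOSB (-3.81, SE 0.72, adjusted p = 0.0348), ATF3 (-2.93, SE 0.55, adjusted p = 0.0348) and GDF15 (-1.43, SE 0.27, adjusted p = 0.0348) fell. The 2 sets shared 5 genes.

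The difference between the stimuli itself was tested as an interaction and was past the threshold for 2 genes (862 at an unadjusted p under 0.05). Both had a more negative late-minus-early change in EGF. They were the transcription factor ZBTB16 (-2.78, SE 0.21, 6.89-fold, adjusted p = 0.0289) and the cytokine-signalling inhibitor SOCS1 (-2.54, SE 0.22, 5.80-fold, adjusted p = 0.038). HBEGF (2.02, SE 0.38, adjusted p = 0.213), FOSB (2.45, SE 0.35, adjusted p = 0.173) and ID1 (-1.54, SE 0.15, adjusted p = 0.054) had interaction values short of it. The 2 calls became 1 without either array of 60 min and 0 without any other stimulated array. As time is a block here, each such omission takes out a whole time pair. Over the alternatives SOCS1 ran from -3.242 to -1.576 and ZBTB16 from -3.262 to -2.037, so their folds depend on the processing.

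The within-stimulus counts leaned on single arrays as well. The 20 in EGF became 2, 1, 1 and 6 without EGF at 20, 40, 240 and 480 min. They became 8, 11, 9 and 10 without serum at 20, 40, 60 and 240 min. The 103 in serum became 54, 59, 67 and 47 without EGF at 20, 40, 60 and 240 min. They became 34, 9, 24, 207, 16 and 38 without serum at 20, 40, 60, 120, 240 and 480 min.

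The largest differences between the stimuli included transcripts that respond to glucocorticoids and cAMP, which were lower after EGF alone. With each EGF array set against the serum array of its time (n = 6 pairs), 10 genes were past the threshold, 1 higher and 9 lower in EGF. The 9 were lower in 6 of 6 pairs each. RGS2, a brake on G-protein signalling (-3.16, SE 0.30, 8.96-fold, adjusted p = 0.0154), and the transcription factor KLF4 (-2.18, SE 0.14, 4.53-fold, adjusted p = 0.00239) differed most. The MAP kinase phosphatase DUSP1 (-1.91, SE 0.16, 3.75-fold, adjusted p = 0.0102) and the cell-cycle inhibitor CDKN1C (-1.85, SE 0.20, 3.61-fold, adjusted p = 0.027) followed. TSC22D3, a glucocorticoid-induced leucine zipper protein (-1.28, SE 0.14, 2.44-fold, adjusted p = 0.027), and the kinase SGK1 (-1.03, SE 0.13, 2.04-fold, adjusted p = 0.0464) were lower as well. So were the anticoagulant receptor THBD (-0.93, SE 0.12, adjusted p = 0.0464), the ETS factor ELK3 (-0.78, SE 0.10, adjusted p = 0.047) and CHML, a Rab escort protein (-0.65, SE 0.08, adjusted p = 0.047). The ETS-family repressor ETV6 was higher in EGF in 6 of 6 pairs (0.77, SE 0.09, 1.71-fold, adjusted p = 0.027).

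Short of the threshold were IER3 (1.43, SE 0.22, adjusted p = 0.0538), GADD45B (-1.51, SE 0.22, adjusted p = 0.0538) and the cornified-envelope gene SPRR1B (-0.99, SE 0.16, adjusted p = 0.0598). FOS was at 0.37 (SE 0.53, adjusted p = 0.736) and MYC at -0.09 (SE 0.16, adjusted p = 0.799).

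**Figure D2:**
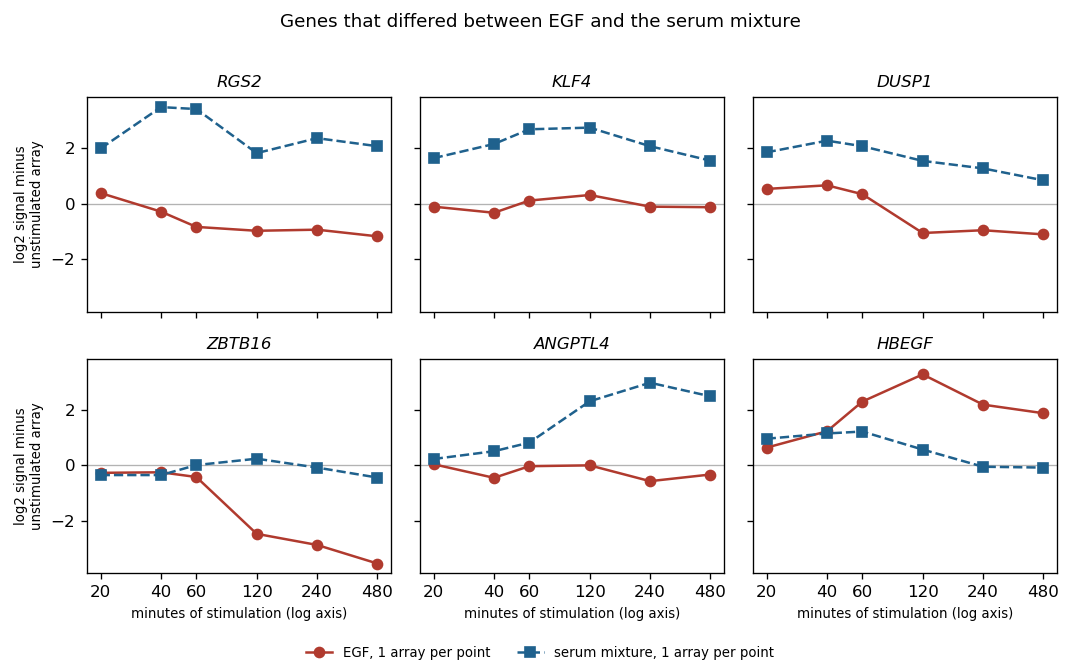
Signal of RGS2, KLF4, DUSP1, ZBTB16, ANGPTL4 and HBEGF minus that of the unstimulated array (log2) against minutes after stimulation on a log axis, 1 point per array, with circles for EGF and squares for serum. HBEGF reached 3.28 in EGF and 0.57 in serum at 120 min.

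As groups, 14 glucocorticoid targets were lower in EGF (median -0.78), with 0 higher and 3 lower past the threshold. When adjusted over the list alone 1 was higher and 8 lower. Camera gave an adjusted p = 5.57e-06, and adjusted p = 0.244 with an estimated correlation. Of 10 cAMP and CREB targets (median -0.66) 0 were higher and 1 lower, and 3 were lower when adjusted over the list alone. For cAMP targets camera gave an adjusted p = 0.000171, and adjusted p = 0.244 with an estimated correlation. Of 11 keratinocyte differentiation markers (median -0.27) 0 had a positive value and 0 were past the threshold, and 6 were lower when adjusted over the list alone. For keratinocyte markers camera gave an adjusted p = 2.4e-05, and adjusted p = 0.244 with an estimated correlation.

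Smaller shifts by camera were found in 5 more lists. The 16 cholesterol and fatty acid synthesis genes had a median of 0.16, with 0 past the threshold and 3 higher when adjusted over the list alone. Camera gave an adjusted p = 0.00689, and adjusted p = 0.253 with an estimated correlation. The 15 AP-1 and delayed early factors had a median of -0.18 and 1 gene lower (camera adjusted p = 0.0342, and adjusted p = 0.244 with an estimated correlation). The 17 FOXO and growth arrest genes had a median of -0.21 and 0 past it (camera adjusted p = 0.0495, and adjusted p = 0.253 with an estimated correlation). The 20 G1 and S phase genes had a median of 0.13 and 0 past it (camera adjusted p = 0.0416, and adjusted p = 0.244 with an estimated correlation). The 17 G2 and M phase genes had a median of 0.07 and 0 past it (camera adjusted p = 0.0402, and adjusted p = 0.44 with an estimated correlation).

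In 6 of 6 time pairs 8 of the 26 list means were lower in EGF. They were those of glucocorticoid, cAMP, keratinocyte, AP-1, mRNA decay, TGF-beta, FOXO and other fast transcripts. Another 3, of cholesterol synthesis, G1 and S phase, and G2 and M phase, were higher in 6 of 6. Each of these 11 had a sign flip exact p = 0.0312 (two-sided), the smallest that 64 flips can give, and an adjusted p = 0.0739. So 8 of 26 lists passed by camera, and 0 of 26 with an estimated correlation or by sign flips.

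**Figure D3:**
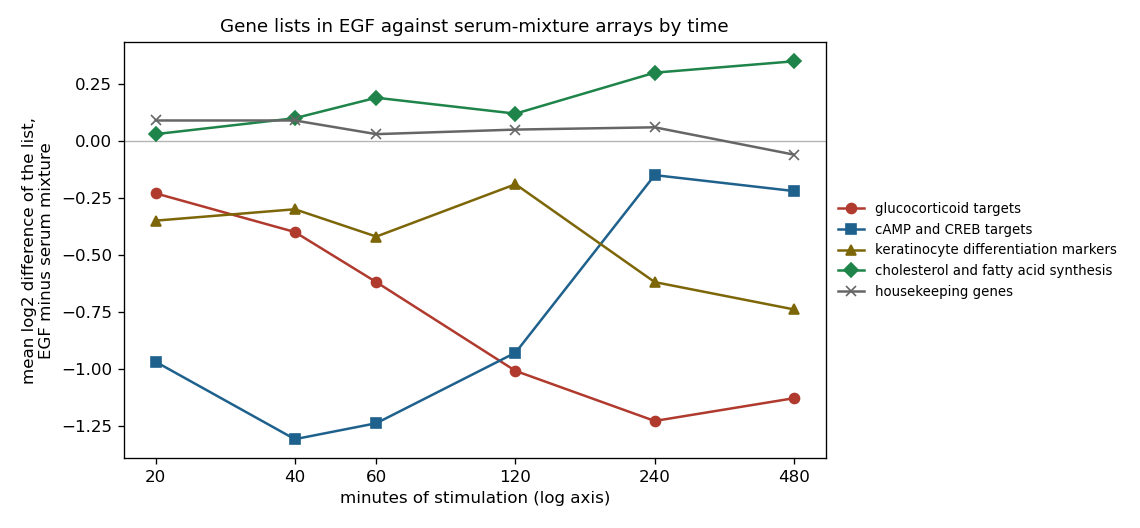
Mean EGF-minus-serum difference (log2) of the genes in 5 lists against minutes after stimulation on a log axis, 1 point per time pair of arrays. The glucocorticoid list went from -0.23 at 20 min to -1.13 at 480 min and the cAMP list from -0.97 to -0.22, beside housekeeping genes at 0.09 and -0.06.

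The other lists were not past the threshold by camera between EGF and serum. Counts past the gene threshold, higher and lower, were 0 and 1 each for immediate early factors (KLF4, adjusted p = 0.0893), MAP kinase phosphatases (DUSP1, 0.302) and other attenuators (RGS2, 0.945). They were 0 and 0 for mRNA decay factors (0.0756), other fast transcripts (0.0645), EGF family genes (0.547) and cytokines (0.0993). They were also 0 and 0 for SRF, MRTF and YAP targets (0.218), TGF-beta targets (0.0756), ribosome biogenesis genes (0.942), proteolysis and migration genes (0.64) and glycolysis genes (0.325). The same held for p53 targets (0.942), interferon response genes (0.871), stress response genes (0.547), basal markers (0.235) and luminal markers (0.174). Housekeeping genes had 0 and 0 (0.64) with a mean of 0.042. Of the 4 tested markers of other cell types 0 were past it.

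The count of 10 genes became 29 without either array of 20 min. It became 1 without EGF at 40, 240 or 480 min or serum at 240 or 480 min, and 2 without either array of 120 min. It became 3 without EGF at 60 min or serum at 40 or 60 min. KLF4 was past the threshold in each. As time is a block, each omission of a stimulated array takes its whole time pair out of this comparison. Without the filter on dim genes the count was 1 and with a stricter one 225. With the stimulus fitted within each phase the same difference gave 100.

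From 20 to 60 min, most values of cAMP-responsive and immediate early genes were lower in EGF, though limma called 0 genes (n = 3 pairs). There were 1115 at an unadjusted p under 0.05, the smallest adjusted p was 0.0547, and 178 were called with a variance trend and robust variances. RGS2 was at -3.21 (SE 0.46, adjusted p = 0.135) and FOSB at -2.39 (SE 0.24, adjusted p = 0.059). KLF4 was at -2.26 (SE 0.21, adjusted p = 0.0547) and the stress-induced factor ATF3 at -2.45 (SE 0.28, adjusted p = 0.0849). Among 10 cAMP and CREB targets 0 had a positive value and 7 were lower in EGF when adjusted over the list alone (mean -1.18, median -0.79). Among 16 immediate early factors 4 had a positive value, and 2 were higher and 5 lower when adjusted over the list alone (mean -0.67, median -0.30). The lists overlap, so they are not separate groups of genes. FOSB is in both, as are NR4A1, NR4A2 and NR4A3 where tested, and KLF4 and ATF3 are in the latter. The count of 0 became 1 without either array of 20 or of 480 min.

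From 120 to 480 min, 58 genes were past the threshold (n = 3 pairs), 19 higher in EGF and 39 lower. The EGF-receptor ligand HBEGF was higher in EGF (2.30, SE 0.27, 4.92-fold, adjusted p = 0.0232). So were the secreted factors STC1 (1.76, SE 0.26, 3.40-fold, adjusted p = 0.0445), GDF15 (1.75, SE 0.22, 3.37-fold, adjusted p = 0.0268) and VEGFA (1.26, SE 0.15, adjusted p = 0.0241). The cytokines CXCL8 (1.48, SE 0.21, 2.79-fold, adjusted p = 0.0442) and IL1B (1.05, SE 0.16, adjusted p = 0.0453) were higher too. Also higher were the MAP kinase phosphatase DUSP4 (1.43, SE 0.13, 2.69-fold, adjusted p = 0.0169) and the ERK-pathway inhibitor SPRED2 (0.76, SE 0.11, adjusted p = 0.0407). The cystine transporter SLC7A11 (1.36, SE 0.18, adjusted p = 0.0335) and the sterol sensor INSIG1 (0.93, SE 0.12, adjusted p = 0.0241) were higher as well.

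Lower in EGF at these times were ANGPTL4, an inhibitor of lipoprotein lipase (-2.90, SE 0.25, 7.44-fold, adjusted p = 0.014), and ZBTB16 (-2.87, SE 0.15, 7.30-fold, adjusted p = 0.00239). RGS2 (-3.12, SE 0.46, 8.67-fold, adjusted p = 0.0445) and DUSP1 (-2.26, SE 0.15, 4.78-fold, adjusted p = 0.00681) were lower too. So were the inhibitors of differentiation ID1 (-1.44, SE 0.11, adjusted p = 0.00681) and ID3 (-1.88, SE 0.20, adjusted p = 0.0215). The growth-arrest gene GADD45B (-1.99, SE 0.21, adjusted p = 0.0204), the sulfate transporter SLC26A2 (-1.92, SE 0.22, adjusted p = 0.0219) and the desmosomal cadherin DSG3 (-1.04, SE 0.16, adjusted p = 0.049) were also lower.

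Of 14 glucocorticoid targets in these late arrays, 1 had a positive value. Past the threshold 0 were higher and 5 lower (median -1.02), and when adjusted over the list alone 1 was higher and 11 lower. Against the unstimulated array the list's median in EGF was -0.01, -0.05, -0.05, -0.33, -0.84 and -0.99 from 20 to 480 min. In serum it was 0.09, 0.20, 0.31, 0.20, 0.24 and 0.15. Cytokines and NF-kB targets had 2 genes higher and 0 lower (8 and 3 when adjusted over the list alone). EGF family genes had 1 and 0 (3 and 0 when adjusted over the list alone).

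The set of 10 genes over all times and this late set of 58 shared 5. The late count became 12 without either array of 40 min, 37 without either of 60 min, and 14 without EGF or 16 without serum at 120 min. It became 0 without either array of 240 min and 2 without either of 480 min. With time as a block, leaving out 1 array takes its whole time pair out of the comparison, so these omissions show the loss of a pair. ZBTB16 was past the threshold under each processing alternative tried, and without the filter on dim genes it was the 1 gene left. Of 31 genes named past the threshold in this comparison 0 stayed past it under every single-array omission.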

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

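The test of the conflicting label of the EGF array of 20 min was chosen after the result was seen, and the counts over swaps and splits of the arrays were planned.

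ZBTB16 and SOCS1 stood out because their late-minus-early change differed between the stimuli: the interaction was -2.78 (adjusted p = 0.0289) for ZBTB16 and -2.54 (adjusted p = 0.038) for SOCS1. Over the 32 swaps of EGF and serum within time points, 2 gave at least 2 genes in the interaction, the real one included, so by the share of 2 in 32 chance was not excluded. The other, with 100 genes, exchanged the labels of all late pairs. It thus measured the plain difference between EGF and serum, with the stimulus fitted within each phase, and is no example of an arbitrary grouping. Fitted with a single stimulus term that difference gave 10 genes, so its count depends on the model. Every remaining swap gave 0 or 1 genes. Without either array of 60 min 1 gene was called, and without any other stimulated array 0 were called by limma (862 at an unadjusted p under 0.05 with all arrays).

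For 8 more genes each late array of one stimulus lay above, and each late array of the other below, all early arrays of its stimulus, while the interaction itself was short of the threshold. The interaction was positive for STC1 (1.76, adjusted p = 0.244), DUSP4 (0.91, adjusted p = 0.244), SLC7A11 (1.29, adjusted p = 0.226), VEGFA (1.40, adjusted p = 0.199) and INSIG1 (0.93, adjusted p = 0.199), which were higher late after EGF and lower late after serum. It was negative for ID3 (-1.36, adjusted p = 0.244), SLC26A2 (-1.34, adjusted p = 0.272) and ABLIM3 (-2.07, adjusted p = 0.199), which moved the other way. In 3 late against 3 early arrays a full separation arises by chance in 10% of genes in each stimulus, and these genes were looked at because they were past another threshold.

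Among the probe sets left out of the gene tests because they carried no single symbol, 1 without any symbol here was past the threshold at 60 min, at 3.16 (SE 0.33, adjusted p = 0.0336 over 13329 probe sets, of which 1584 carried no single symbol). The late-minus-early comparison called 427 probe sets, 49 of them without a single symbol, and EGF minus serum called 8, with 1 such.

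The EGF array of 20 min carried 20 min in its title and 40 min in its description. If it were a second 40 min array, its difference from the EGF array of 40 min would be unrelated to the same difference in serum; across 43 fast-responding genes the correlation was r = 0.232 (rho 0.332, permutation p = 0.065, one-sided, over 1e+05 resamples). The median of the 16 immediate early factors was 0.71 higher at 40 min than at 20 min after EGF and 0.52 higher after serum, and 13 of 16 were higher at 40 min after EGF. A true 20 min array and a second 40 min array cannot be told apart from these values, as 1 array per time leaves no spread to set them against. No biological explanation was tested.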

How the results depend on the processing

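The fits with both arrays of 20 min left out, the sign flips, fry and the splits of whole time points were chosen after the result was seen. Of the genes named past a threshold (all comparisons but the early part of EGF minus serum, which had none, and change between times, which has no direction), 1 changed direction. PPP2R5D, higher late than early in serum (1.07, and 1.14 without serum at 20 min), was at -0.16 without EGF at 20 min and at -0.10, -0.25 and -0.12 without serum at 120, 240 and 480 min. In these 4 fits another probe set of the gene had become its brightest, and with the first probe set kept the values were 0.89 to 1.18. The value of CYP1A1 in the late part of EGF minus serum, 1.88, ran from 1.03 to 3.03, and its call was lost in 10 omissions and 3 settings. Other named values moved too. SPRED2 late minus early in EGF ran from 0.153 to 0.909, GDF15 in the late part of EGF minus serum from 0.846 to 1.976 and SOCS1 in the interaction from -3.242 to -1.576. CCN2 at 40 min stayed at 3.173 to 3.267. Counts moved as well: the numbers of called genes depended on the filter, the variance model, the offset and single arrays, and the cause was not tested unless stated. Precision was limited by 1 array per stimulus and time, and for dim genes by background, as 33.3% to 40.0% of probe sets had a signal under 20.

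Without an offset the interaction gave 0 genes, EGF minus serum 6 and its early part 1. With 4 times the offset the responses gave 1 at 20 min, 6 at 120 min, 1 at 240 min and 2 at 480 min, change between times 18, late minus early in serum 199, the interaction 8, EGF minus serum 157 (all 10 kept), its early part 6 and its late part 167. Without quantile normalization the interaction gave 1, the early part 2 and 11 lists were past the threshold late minus early; 247 of the 268 genes late minus early, 8 of 10 in EGF minus serum and 55 of 58 in its late part were kept. Without the filter on dim genes the responses gave 0, 2 and 1 at 20, 60 and 120 min, late minus early 67, in EGF 8, in serum 10, the interaction 0, EGF minus serum 1 and its late part 1; with the stricter filter they gave 7, 1 and 5 at 120, 240 and 480 min, change between times 35, late minus early 576, in EGF 57, in serum 295, the interaction 5, EGF minus serum 225, its early part 9 and its late part 285. With the mean of a gene's probe sets change between times gave 5, the interaction 1, EGF minus serum 30 and its early part 2.

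With a variance trend and robust variances the 6 responses gave 5, 20, 28, 26, 35 and 46 genes from 20 to 480 min, change between times 165, late minus early 647, in EGF 69, in serum 412, the interaction 70, EGF minus serum 426, its early part 178 and its late part 554; 258 of 268, 10 of 10 and 58 of 58 genes were kept in late minus early, EGF minus serum and its late part. Requiring 1.5-fold left 100 genes late minus early, as fewer genes reach that size. Without time as a block EGF minus serum gave 57, its early part 7 and its late part 144. With time as a factor late minus early gave 147, without FOS, ATF3, MDM2, ERBB3, ZBTB16 and ANGPTL4, and with 240 and 480 min against 20 and 40 min it gave 163. Without both arrays of 20 min the responses gave 3 at 40 min, 3 at 60 min and 1 at 120 min, late minus early 71, in EGF 0, in serum 18, the interaction 0, EGF minus serum 29 and its early part 1, with fewer arrays in each fit.

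Lists past the threshold fell from 7 to 0 late minus early and from 8 to 0 in EGF minus serum with an estimated correlation. Exact sign flips of the 6 pairs gave 0 lists in EGF minus serum, and 64 flips allow no raw exact p under 0.0312. The rotation test fry gave 10 lists late minus early, 6 of the 7 called by camera (not cytokines, adjusted p = 0.114), and among the others called housekeeping genes (higher late, adjusted p = 0.0309). In EGF minus serum it gave 12, 7 of the 8 called by camera (not G2 and M phase, adjusted p = 0.073), with 0.0298 for glucocorticoid and cAMP targets and 0.0125 for keratinocyte markers. The profile correlation of 0.164 was 0.063 without the filter, 0.137 without an offset, and 0.136 to 0.184 with 1 time left out.

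With 1 array left out the counts ran from 0 to 2, 1 to 6, 1 to 7 and 1 to 2 for the responses at 20, 40, 60 and 120 min and were 0 at 240 and 480 min (limma; 752 and 910 genes at an unadjusted p under 0.05 with all arrays). They ran from 2 to 4 for change between times, 56 to 437 late minus early, 1 to 29 in EGF, 9 to 207 in serum, 0 to 2 for the interaction, 1 to 29 for EGF minus serum, 0 to 1 for its early part and 0 to 58 for its late part. Of the named genes, 12 of 38 late minus early, 1 of 16 in EGF, 7 of 20 in serum, 1 of 10 in EGF minus serum (KLF4) and 0 of 31 in its late part were past the threshold in every such omission. In EGF minus serum, its parts and the interaction, each omission of a stimulated array removes a whole time pair and a residual degree of freedom.

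The real groups were compared with other groupings of the same arrays. In EGF minus serum 1 of 32 swaps within time points, the real one, gave 10 genes (highest other 1), the smallest share these swaps can give. Of 100 splits ignoring time, 1 gave as many (highest other 2). These kept time as a block, so splits with both arrays of a time on one side rest on fewer pairs and tend to call fewer genes. The real grouping gave the most genes, but chance is not excluded by these counts. Late minus early gave 268 in 1 of 100 splits drawn within each stimulus (highest other 21), but these ignore that EGF and serum arrays share their time points. The splits of the 6 whole time points number 10, too few for a share under 0.05 (real 268, highest other 2). The splits of 6 arrays also number 10, too few for such a share: late minus early gave 20 in EGF (highest other 0) and 103 in serum (highest other 1), and EGF minus serum gave 0 in the early part (highest other 0, as many in 10 of 10) and 58 in the late part (highest other 0).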

Other observations

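The tests of housekeeping genes, of RNA integrity pair by pair, of hydrocortisone and of the unstimulated array's level were chosen after the result was seen; the actin covariate and the question of fading levels were planned.

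The mean of the glucocorticoid targets declined with time after EGF. The mean of the 14 tested genes against the unstimulated array was 0.01, -0.01, -0.11, -0.64, -0.88 and -0.99 from 20 to 480 min after EGF, and 0.24, 0.39, 0.51, 0.37, 0.35 and 0.14 after serum. The list was singled out for this course after its late values had been seen, so no test of the trend is given. Late minus early in EGF, ZBTB16 and DUSP1 were the 2 list members past the threshold, while the metallothioneins had values near 0, with MT2A at 0, MT1X at 0.06 and MT1E at -0.05. In serum several members were lower late as well, with SGK1 at -1.27 (-1.02 in EGF), DUSP1 at -0.85, CEBPD at -0.72, KLF9 at -0.68 and TSC22D3 at -0.65, while ANGPTL4 was at 2.08, so the serum mean is not that of a list standing still.

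The lower level of glucocorticoid targets in EGF than in serum was weighed against technical explanations. Overall signal or normalization of the 2 series would move housekeeping genes alike, and their mean difference was 0.042. But the values had been scaled and quantile normalized beforehand, which holds such a mean near 0. The median difference over all tested genes was 0.007. The housekeeping mean therefore cannot exclude that explanation. The planned covariate, the log2 ratio of actin 3' to 5' signal, hardly differed on average (0.56 after EGF, 0.59 after serum) and so could not move the list's difference much (-0.729 with it, -0.769 before). A line over the 6 pairs gave a list difference at equal ratio of -0.73 (SE 0.15) for actin and -0.75 (SE 0.09) for GAPDH. As the ratios hardly differed on average, such a line had to give nearly the list's mean, so it does not test RNA integrity. At 20 min both ratios were higher in EGF (log2 0.237 for actin, 0.232 for GAPDH) with the list at -0.23. At 120 min both were lower (-0.299 and -0.217) with the list at -1.01. The list's difference did go with the GAPDH ratio (r = 0.88 over 6 pairs, 0.59 for actin), and both went with log2 time (r = -0.79 for the ratio, -0.95 for the list), so a part of RNA integrity in how the difference changed with time cannot be told apart from time. The hydrocortisone in the mixture may contribute as a hypothesis, but the late mean of -1.12, the lowest of 26 lists, is the observation that prompted it, over all times the cAMP list lay lower (-0.805), and hydrocortisone cannot be told apart from horse serum, insulin and cholera toxin without arrays that part them.

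In the late EGF arrays the glucocorticoid list lay below the unstimulated array. That the unstimulated array alone was too high was argued against by the early EGF arrays, whose mean was -0.03 against the same array. The late mean was -0.84, and a fading of levels left from the earlier medium, which held hydrocortisone, cannot be told apart from an effect of EGF, because none of the 13 arrays was unstimulated at a later time. After serum the early mean was 0.38 and the late mean 0.29.

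The cAMP list and the immediate early list, which share FOSB and NR4A genes, differed early instead. The mean difference between EGF and serum from 20 to 480 min was -0.97, -1.31, -1.24, -0.93, -0.15 and -0.22 for the former and -0.84, -0.74, -0.45, -0.29, -0.07 and 0.07 for the latter. The mean of EGF family genes went from -0.18 at 20 min to 0.63, 0.37 and 0.49 at 120, 240 and 480 min. HBEGF, 1 of these 7 genes, had a late difference of 1.334 to 2.476 over the alternatives and so weighs heavily in that mean. The list's median against the unstimulated array was 0.97, 0.96 and 0.71 at these times in EGF, and 0.57, 0.07 and -0.08 in serum.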
